A study of Mus musculus with 8 samples.

How the data were processed

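Single-cell RNA was sequenced from whole mouse kidneys of 4 genotypes: wild type (WT), knockout of Adh5, knockout of Csb, and the double knockout of both genes. Adh5 encodes alcohol dehydrogenase 5, which removes formaldehyde, and Csb (gene symbol Ercc6) encodes a protein of transcription-coupled DNA repair. Per the labels' protocols, all mice received methanol before the kidneys were collected, the tissue was digested with liberase, the kidneys of at most 6 mice made 1 pool of cells, and a pool was loaded on 2 lanes of the 10x instrument. Each genotype has 2 libraries, which were therefore read as 2 lanes of 1 pool. The number of replicates is then 1 pool per genotype, so no p-value between genotypes is given. Read so, libraries 1 and 2 measure technical variation only, and the number of mice in each pool and their sex are not given in the sources used here.

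The deposited values are UMI counts per gene and cell barcode, which the authors made with Cell Ranger as filtered feature-barcode matrices, per the labels. CASAVA is named as a second tool and the genome build is mm10, per the submitters' processing notes. Tool versions and the annotation release are not given in the sources used here. The matrices list 31053 genes. Gene positions were taken from GENCODE M21 on the same build by gene identifier, which matched 30934 genes (99.6%).

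Cells were kept with at least 500 UMIs, at least 250 detected genes and at most 50% mitochondrial UMIs. The wide mitochondrial limit was chosen because tubule cells hold many mitochondria. Doublet scores came from Scrublet as built into Scanpy 1.11.5, run per library. The share removed per library was the loading estimate of 0.8% per 1000 barcodes, because the automatic thresholds marked between 0.0213% and 28.8% of cells in libraries of similar size. Counts were scaled to 10000 per cell and logged for clustering. The 2000 most variable genes, 40 principal components, 15 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9) gave the clusters. A cluster received the name of a cell class where at least 3 of the class's fixed markers were raised at least 2-fold, where its 10 leading genes held no more markers of another class than of its own, and where it held at least 20 cells. Proximal tubule was assigned last, where the best matching other class had under 3 raised markers. Its own markers were read against the lower quartile over clusters, and those of other classes against all other cells. Markers of proliferating cells and of parietal epithelium named no cluster. Names such as proximal tubule cell therefore mean proximal tubule-like by these markers. A list of leading genes that withheld names from clusters was written after the clusters were seen, and the share of cells in unnamed clusters is given per genotype.

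UMI counts were summed per library and cell class and scaled to CPM (UMIs of a gene scaled to a fixed library total) with TMM factors from edgeR 4.0.16 over the 8 libraries. A gene was measured in a comparison where its CPM was at least 10 in 1 of the pools compared and at least 50 UMIs were counted over both. It was called higher or lower where log2(CPM + 1) differed by at least 1, a 2-fold threshold, and both libraries of one genotype lay beyond both libraries of the other. For the double knockout against all other genotypes, the difference to the nearest of the other pools was used. The excess over additivity is the log2 value of the double knockout minus that of each single knockout plus that of WT, given with no test. Poisson intervals of counts and folds and Clopper-Pearson intervals of shares, all at 95%, cover counting error only. A fold against a pool with no counts was computed against a floor of 3 counts over the pool and is a lower bound.

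Proximal tubule cells, the most frequent class, were compared for the 3 knockouts against WT, for the double knockout against each single knockout and against all other genotypes. Other classes with at least 50 cells in every pool were compared by the same rule and are given against WT. Shares of cells were called different at a 1.5-fold difference from WT. For 7 genes, the share of cells with at least 1 UMI was taken after each cell was thinned to 1000 UMIs. The same share was read in lymphocytes, which should lack tubular transcripts but can express Mdm2 and Ddit3, and possibly Cdkn1a, themselves.

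The 22 fixed gene lists were p53 targets, the integrated stress response, secreted stress factors and cytokines, tubular injury, proximal tubule transport and metabolism, fatty acid oxidation and fasting, formaldehyde and alcohol metabolism, NRF2 targets and glutathione, nucleotide excision repair, DNA crosslink repair and damage signalling, immediate early and heat shock genes, interferon response, antigen presentation, cell cycle, senescence, fibrosis and matrix, male-biased and female-biased proximal tubule genes, Y-linked genes, X inactivation, haemoglobin, and mitochondrially encoded genes. The markers of the proximal tubule segments S1 and S3 were read as 2 further lists. For each list the numbers of measured members called higher, lower or neither were read. The percentile of the median log2 fold change was taken among 10000 random lists of the same size matched on mean expression. Not every list is named for every comparison below, so a list left out is not thereby unchanged. The percentile describes these libraries and is not a p-value.

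Genes to name were chosen by a fixed rule. In each proximal tubule comparison these were the 12 genes with the largest log2 fold change in each direction among the calls (10 for the comparison with all other genotypes), without unnamed predicted genes. Adh5, Ercc6, and from each list the 4 measured members with the largest change in the double knockout against WT were added. Gdf15, Cdkn1a, Mdm2, Havcr1, Lcn2, Ddit3, Trib3 and Fgf21 were read in every comparison. In other classes, the 3 largest changes in each direction and the same 8 genes were taken. The comparisons, rules of size, gene lists, markers, rule for named genes and most alternatives were fixed before the data were examined.

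Library depth ran from 17035309 to 130471794 UMIs, and the libraries of a genotype were compared with each other before any genotypes were. The rule of size was tested on simulated data, in which 200 genes were changed by 3-fold or 5-fold in counts drawn from the real library means. In double knockout against WT, 100% of the changed genes of each size and direction were recovered among 6412 measured genes. In Adh5 knockout against WT, 98% of the 5-fold lower genes were recovered among 6425 measured genes, and 100% of the others. Unchanged genes called numbered 0 in each of the 5 simulated comparisons of 2 pools. The simulation covers counting error only, with no variation between pools, and its changes lie above the 2-fold threshold.

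The alternatives were other scalings (plain CPM, CPM without mitochondrially encoded genes, DESeq2 1.42.0 size factors), a pseudocount of 5 CPM, minimums of 30 and 1 CPM, a stricter cell filter of at least 1000 UMIs and at most 25% mitochondrial UMIs, doublets kept, counts thinned to one total, all filtered cells in place of proximal tubule cells, other cluster resolutions of 0.5 and 2, thinning to 500 UMIs or none for shares of cells with a UMI, leaving out each library, and edgeR and DESeq2 fits that count libraries as samples. A floor of 2000 UMIs per cell, shares without clusters holding tubular RNA, and proximal tubule cells without the clusters led by Havcr1 or Spp1 were added after seeing the data, as were gene lists limited to members at 10 CPM or more in WT. No reads were aligned, and RNA splicing, spliced fractions and sequence variants were not analysed here. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and in R 4.3.3, with matplotlib 3.10.9 for figures. Random draws used seed 1.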

Results

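Kidney cells of methanol-treated mice were profiled by droplet single-cell RNA sequencing in 4 genotypes, with 2 libraries each. The wild-type (WT) libraries held 20745 and 20658 barcodes with 128503669 and 125084413 UMIs. The 2 Adh5 knockout libraries were unequal, with 1802 barcodes and 17035309 UMIs in library 1 and 20817 barcodes and 130471794 UMIs in library 2. The Csb knockout libraries held 18422 and 19796 barcodes with 117942751 and 124668417 UMIs, and the double knockout libraries 19359 and 18486 barcodes with 111168555 and 104315169 UMIs. After filtering and doublet removal, 32213 WT, 18558 Adh5 knockout, 31297 Csb knockout and 31511 double knockout cells remained. Of these, 23765, 14411, 23522 and 22029 were proximal tubule cells. Both libraries of a genotype were read as lanes of 1 pool of mice from the protocol, which leaves no replicates (n = 1 pool per genotype).

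Between the libraries of a genotype, gene counts in proximal tubule cells varied little in WT, with a chi-square per degree of freedom of 2.44 where random splits of the cells gave 1.24 to 1.90. The values were 2.17 in the Csb knockout and 3.92 in the double knockout, against up to 2.11 and 3.01 in random splits. The 2 Adh5 knockout libraries differed more, with 29.1 against at most 2.29, so it is not certain that they are lanes of 1 pool. Between genotypes the value ran from 51.2 to 297. In the Adh5 knockout, 25 genes stood at least 2-fold apart between the libraries, among them Gstp1 of glutathione conjugation at 164 and 54.8 CPM. In the double knockout this held for 1 gene, the injury marker Lcn2, at 6.81 and 15.6 CPM. These genes were chosen after their values were seen.

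Adh5 (ENSMUSG00000028138, build mm10, chromosome 3, 138443093 to 138455499) was read first as a check of the labels. In proximal tubule cells it stood at 359 CPM in WT and at 11.7 CPM in the Adh5 knockout (3.26% of WT) and 8.54 CPM in the double knockout (2.38%). In the Csb knockout, in which Adh5 is not listed as targeted, it stood at 165 CPM, or 46.1% of WT. The Csb gene Ercc6 (ENSMUSG00000054051, chromosome 14, 32513521 to 32580990) had 6.21 CPM in WT, 5.62 in the Adh5 knockout, 4.08 in the Csb knockout (65.7%) and 3.73 in the double knockout (60.1%). These are 3′ tags and the deleted part of Ercc6 is not given in the sources used here, so the Ercc6 counts do not check the Csb labels. The Y-linked helicase gene Ddx3y stood at 31.7 to 37.8 CPM in the 4 pools, and Xist, the RNA of the inactive X chromosome, at 0.0692 to 0.127 CPM.

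The Adh5 knockout was compared with WT for the effect of losing Adh5 without loss of Csb. Cdkn1a, the p53 target that encodes the cell cycle inhibitor p21, rose from 4.90 to 31.5 CPM, 6.42-fold (95% Poisson interval 5.93 to 6.97). Gdf15, a secreted stress factor, rose 2.31-fold to 42.4 CPM. Cyp4a12a, which hydroxylates fatty acids, was 3.15-fold higher, Mdk, a heparin-binding growth factor, 2.88-fold, and Hsd11b1, which activates glucocorticoids, 2.81-fold. The immunoglobulin transcripts Igkc and Igha, products of B lineage cells, were 4.98-fold and 6.21-fold higher. Tmem45b, Ccl28, Kif20b, Pcdh7, Selenbp2 and Dhx9 completed the 12 largest increases, at 2.56-fold to 4.51-fold.

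Besides Adh5 itself, Pck1, which encodes the key enzyme of gluconeogenesis, fell 3.21-fold, from 1766 to 549.8 CPM. Id3 and Id1, inhibitors of basic helix-loop-helix factors, fell 3.94-fold and 3.79-fold, and Gsta2, a glutathione transferase, 3.52-fold. Car3, a carbonic anhydrase, was 3.04-fold lower, and the very long genes Lrmda and Fhit 9.98-fold and 3.51-fold. Fam25c, Rdh16f2, Lamtor3 and Rarres2 were 2.73-fold to 4.37-fold lower. All 4 measured haemoglobin genes, whose RNA comes from red blood cells, were lower, with a median log2 fold change of −1.24. Cluster 5 of the class, led by Car3 and Gsta2, held 3.64% of Adh5 knockout and 7.33% of WT proximal tubule cells, and cluster 6 9.97% and 5.34%, so these values mix cell make-up with expression. By the rule of size, 22 of 6819 measured genes were higher and 31 lower, and 6766 were neither. Without Adh5 knockout replicate 2, which leaves the small library, 52 genes were higher and 55 lower, and Lamtor3, which lies near Adh5, no longer met the rule (log2 −0.87). Id1 (−0.41) did not meet it when all cells were summed, Pcdh7 (0.97) and Hbb-bt (−0.83) under a pseudocount of 5, nor Hbb-bt (−0.95) under the stricter cell filter.

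Among the lists in this comparison, 2 of 15 measured p53 targets were higher (Cdkn1a and Gdf15), none was lower, and the median of 0.29 lay at percentile 100. Of 4 measured senescence genes 2 were higher, the same Cdkn1a and Gdf15, with a median of 0.71 at percentile 100. Counting only members at 10 CPM or more in WT leaves Cdkn1a out and gives a median of 0.26 over 3 senescence genes. Fatty acid oxidation genes had a median of −0.14 at percentile 0.01, with 1 of 17 lower (Cyp4a10 at −1.27, named after its value was seen). Mitochondrially encoded genes had a median of −0.32 at percentile 0.02. The median mitochondrial share per barcode was 26.3% and 26.8% in the WT libraries and 18.7% to 23.2% in the knockout libraries. A trait of the WT pool can therefore not be told apart from genotype where this list is lower against WT. Formaldehyde and alcohol metabolism genes had a median of −0.20 at 0.06, NRF2 and glutathione genes −0.17 at 0.11 and male-biased genes 0.25 at 99.97. S1 segment markers had a median of −0.26 at percentile 0.04 and S3 markers 0.24 at percentile 99.9, with no member called in either. Tubular injury genes had a median of 0.18 at percentile 99.05, with none of 6 called. Integrated stress response genes had 0.11 at percentile 98, with 1 of 12 higher.

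The Csb knockout was compared with WT for the effect of losing Csb. Adh5 was also at 46.1% of WT in this pool, so the effect is not that of Csb loss alone. Cdkn1a rose 2.78-fold (2.55 to 3.02), from 4.90 to 13.6 CPM, and Gdf15 2.06-fold to 37.7 CPM. The immunoglobulin transcripts Igkc and Igha were 6.31-fold and 7.74-fold higher. Ctxn3, a small membrane protein of the kidney and brain, was 4.61-fold higher, Cyp4a12b and Cyp4a12a 4.37-fold and 3.01-fold, Mdk 3.08-fold, the chemokine Ccl28 3.24-fold and Il34, a macrophage growth factor, 2.14-fold. Fam25c fell 4.20-fold, Ugt2b37, a glucuronosyltransferase, 3.16-fold, Car3 2.65-fold, Pck1 2.56-fold, Id1 2.61-fold and Id3 2.44-fold. The mitochondrially encoded mt-Nd3 was 2.16-fold lower, Sardh, which releases formaldehyde units from sarcosine, 2.11-fold, and Adh5 2.17-fold. Of 6791 measured genes, 13 were higher and 14 lower. Cdkn1a, Gdf15, Igkc, Igha, Cyp4a12a, Mdk, Ccl28, Fam25c, Car3, Pck1, Id1, Id3 and 3 haemoglobin genes were called the same way in the Adh5 knockout. For such shared changes a trait of the WT pool cannot be told apart from genotype.

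Several of these calls stood close to the threshold. Gdf15 had log2 0.99 without WT replicate 1 and 0.87 under a pseudocount of 5, Il34 0.97 without WT replicate 2, 0.76 under a pseudocount of 5 and 0.95 under the stricter filter, both 0.99 without Csb knockout replicate 2, mt-Nd3 −0.88 under the stricter filter and Sardh −0.97 under plain CPM. Summed over all cells, Cdkn1a (0.82), Gdf15 (0.93), Id1 (−0.45) and Id3 (−0.90) no longer met the rule. Nor did the haemoglobin genes Hbb-bs (−0.78), Hba-a1 (−0.66) and Hba-a2 (−0.68). A pseudocount of 5 gave Cdkn1a 0.91 and Id1 −0.98.

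Of 14 measured p53 targets 2 were higher in the Csb knockout, with a median of 0.12 at percentile 99.7, and of 12 integrated stress response genes 1 was higher, with a median of 0.22 at percentile 100. Of 4 secreted factors 2 were higher (Gdf15 and Il34), with a median of 0.55 at percentile 100. Gdf15, close to the threshold, is a call counted in all 3 lists, and over the 3 secreted factors at 10 CPM or more in WT the median was 0.10 at percentile 86.1. Haemoglobin genes had a median of −1.24 with 3 of 4 lower, and mitochondrially encoded genes a median of −0.34 at percentile 0 with mt-Nd3 alone called. Formaldehyde and alcohol metabolism genes had −0.20 at percentile 0, with Adh5 alone called, and fatty acid oxidation genes −0.09 at 2.18. Senescence genes had 0.75 at percentile 100 (Cdkn1a and Gdf15 called of 4) and tubular injury genes 0.19 at 99.81 (1 of 6 higher). Antigen presentation genes had 0.22 at 99.99 and cell cycle genes 0.39 at 99.95, with no member called.

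**Figure D1:**
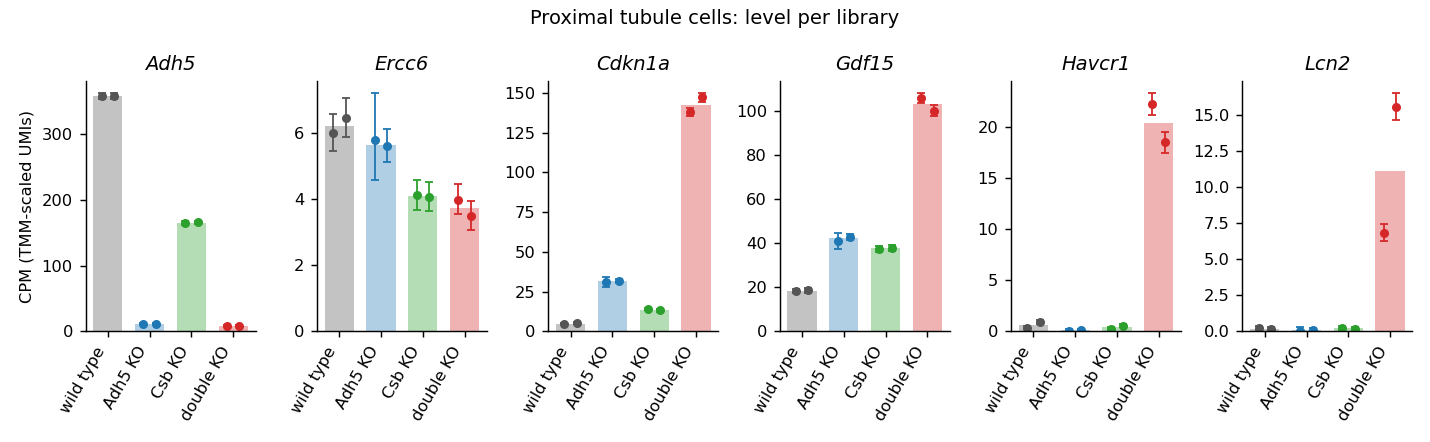
Expression of 6 genes in proximal tubule cells, in CPM, for the 4 genotypes, with a bar per pool and a point per library. Cdkn1a stands at 4.90 CPM in WT, 31.5 in the Adh5 knockout, 13.6 in the Csb knockout and 142 in the double knockout.

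The double knockout was compared with WT for the joint effect of both losses. Cdkn1a rose from 4.90 to 142 CPM, 29.1-fold (27.0 to 31.3). Havcr1, the tubular injury receptor KIM-1, rose 33.5-fold to 20.4 CPM (WT libraries at 0.328 and 0.898 CPM), and Lcn2, a secreted siderophore-binding protein of injured tubules, 59.3-fold (40.9 to 89.6) to 11.1 CPM. In B cells, T cells and macrophages of the double knockout Lcn2 stood at 7.38, 5.74 and 5.81 CPM, so free RNA from distal segments can make up part of its rise in the proximal tubule. Gdf15 rose 5.62-fold to 103 CPM, and Phlda3, a p53 target that restrains AKT, 9.86-fold. Spp1, encoding osteopontin, rose from 329 to 2231 CPM, 6.79-fold. Cyp27b1, which makes active vitamin D, was 20.99-fold higher, Cbr3, a carbonyl reductase, 19.4-fold, Ephx1, an epoxide hydrolase, 14.6-fold, and Aldh1a1, an aldehyde dehydrogenase, 7.07-fold. The chemokines Cxcl1 and Ccl2 were 23.9-fold and 12.9-fold higher, and the stress transcription factor Atf3 9.69-fold.

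Gbp2b, an interferon-induced GTPase, rose from 0.0267 to 12.7 CPM (log2 3.73, 4 UMIs in WT). Hspb1, a small heat shock protein, was 9.88-fold higher, Cfi, a complement protease, 9.16-fold, and Dpysl3 12.99-fold. Ddit3, encoding the stress factor CHOP, rose 2.19-fold to 23.8 CPM. Mdm2, another p53 target, was at 27.0 and 38.8 CPM, short of the threshold (log2 0.51). Trib3 and Fgf21 were below the minimum of expression, at 0.602 and 0.138 CPM in the double knockout.

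Adh5 fell 42.0-fold and Hpd, an enzyme of tyrosine breakdown, 17.7-fold, from 26.9 to 1.52 CPM. Car3 fell 8.03-fold, Ndrg2, a stress-regulated gene of differentiated epithelium, 6.53-fold and Dnase1 4.51-fold, from 729 to 162 CPM. The very long genes Lrmda, Fhit and Immp2l fell 9.04-fold, 6.48-fold and 4.64-fold. The haemoglobin genes Hbb-bs, Hba-a2, Hba-a1 and Hbb-bt fell 6.15-fold to 7.77-fold. In all, 124 of 6961 measured genes were higher and 75 lower, and 39 of the higher and 12 of the lower differed more than 4-fold. Cluster 8 of the class, led by Iigp1 and Fgg, held 12.1% of double knockout and 0.900% of WT proximal tubule cells, and cluster 15, with Aldh1a1, Cbr3 and Cyp4a14 among its leading genes, 8.12% and 0.0799%. Clusters 3, 6, 7 and 12 lay mostly in the other pools, so these folds mix cell make-up with expression. Cluster 15 was left out in no alternative. The clusters called led by Havcr1 or Spp1 are 8 and 33, which have either gene among their 10 leading genes. In cluster 8, Spp1 stands behind Iigp1, Fgg, Ifit3, Cxcl10 and Ubd. Leaving it out therefore also removes cells high in interferon response genes.

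With the clusters led by Havcr1 or Spp1 left out, a choice made after seeing them, the folds of Havcr1 (log2 1.79), Lcn2 (2.29), Spp1 (1.31), Gbp2b (1.65), Cxcl1 (2.00), Ccl2 (1.06), Atf3 (1.66), Hspb1 (1.26) and Cfi (1.81) were more than 1.5-fold smaller, and Ddit3 (0.84) no longer met the rule. Summed over all cells, Cdkn1a (3.90), Cbr3 (2.499), Ephx1 (1.72), Hspb1 (1.75), Ndrg2 (−1.49) and Hbb-bs (−2.22) were smaller and Ddit3 (0.88) was not called, nor was it under a pseudocount of 5 (0.86). Lcn2 was 2.72 without double knockout replicate 2, and Ccl2 3.60 without WT replicate 1.

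Of 18 measured p53 targets, 7 were higher in the double knockout than in WT and none lower, with a median of 0.73 at percentile 100; Btg2, an antiproliferative p53 target, was at log2 1.97. Of 15 measured tubular injury genes 12 were higher, with a median of 1.90, among them Tmsb10 at 2.58. Of 8 secreted factors 6 were higher, with a median of 2.59, and of 6 senescence genes 4 were higher, with a median of 2.60. All 7 measured antigen presentation genes were higher, with a median of 1.91, led by Cd74, the invariant chain of MHC class II, which rose from 51.1 to 357 CPM, and by H2-Ab1, from 22.8 to 129 CPM. Of 6 interferon response genes 5 were higher, with a median of 1.68, including Bst2 at 2.503, Cxcl10 at 2.11, Psmb8 at 2.09 and Ifit3 at 1.26. Each of these lists lay at percentile 100. The lists share members, so they are not independent. Cdkn1a and Gdf15 are both p53 targets and senescence genes, and Gdf15, Ccl2 and Cxcl1 are both secreted factors and senescence genes. Lcn2 and Spp1 count as injury genes and secreted factors, and Cxcl10 as a secreted factor and an interferon response gene. Many members pass the minimum of expression only through their rise in the double knockout. Counting only members at 10 CPM or more in WT, a choice made after seeing this, 3 of 5 tubular injury genes (median 1.81), 2 of 3 secreted factors (2.43), 1 of 3 senescence genes (0.52), 1 of 2 interferon response genes (0.83), 3 of 13 p53 targets (0.51) and all 7 antigen presentation genes were higher. Without the clusters led by Havcr1 or Spp1, the median was 0.99 for tubular injury and 1.15 for antigen presentation, the folds of Cd74 (log2 1.95), H2-Ab1 (1.72), Tmsb10 (1.52) and Cxcl10 (1.08) were more than 1.5-fold smaller, and Ifit3 (0.69) was not called. Ifit3 also missed the threshold under a pseudocount of 5 (0.93) and over all cells (0.97), where Cd74 (1.77), H2-Ab1 (1.71), Bst2 (1.41) and Tmsb10 (1.88) were lower.

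Of 13 integrated stress response genes 4 were higher (Ddit3, Atf3, Gdf15 and Phgdh at 1.23), with a median of 0.40 at percentile 100. Of 13 NRF2 and glutathione genes 2 were higher, Ephx1 and Gsta4, with a median of 0.32 at percentile 100. Gsta4, at 1.35, was at 0.94 over all cells. Of 14 immediate early and heat shock genes 3 were higher (Atf3 at 2.61, Ier3 at 1.24 and Klf6 at 1.22), with a median of 0.23 at percentile 99.8, and Ier3 (0.58) and Klf6 (0.57) were not called without the clusters led by Havcr1 or Spp1, nor Ier3 (0.85) under a pseudocount of 5. Of 3 cell cycle genes 1 was higher, Ccnd1 at 1.23 (0.998 over all cells, short of the rule), with a median of 0.45 at percentile 99.6. Cluster 16 of the class, led by the cell division genes Ube2c, Birc5 and Hmmr, held 1.06%, 1.44%, 2.48% and 3.92% of proximal tubule cells in WT, Adh5, Csb and double knockout.

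Proximal tubule transport and metabolism genes had a median of −0.26 at percentile 5.58, with 3 of 27 lower, Pck1 at −1.50, Miox, the first enzyme of inositol breakdown, at −1.39, and Napsa at −1.28. The sulfate transporter gene Slc13a1 was higher at 1.26, and at 0.98 without the clusters led by Havcr1 or Spp1. Markers of the S3 segment had a median of −0.79 at percentile 0, with Cyp7b1 (−1.49) and Slc22a7 (−1.24) called lower of 6 measured. S1 markers had a median of −0.01 at percentile 89.8. Formaldehyde and alcohol metabolism genes had a median of −0.33 at percentile 1.10, with Aldh1a1 higher and Adh5 lower of 15 measured. Fatty acid oxidation genes had a median of −0.09 at percentile 67.3, with 2 of 19 higher, Cyp4a14 at 1.20 and Ucp2 at 1.04. Of the 17 members at 10 CPM or more in WT none was called, with a median of −0.16 at percentile 38.7. Cyp4a14 (0.96) missed the threshold over all cells, as did Ucp2 without the clusters led by Havcr1 or Spp1 (0.90) and without WT replicate 2 (0.96), and both under a pseudocount of 5 (0.83 and 0.82).

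No member was called among 12 nucleotide excision repair genes (median −0.03, percentile 59.1), 4 crosslink repair and damage signalling genes (0.11, percentile 76.2), 7 male-biased genes (−0.33, percentile 9.89) or 3 Y-linked genes (−0.03, percentile 44.4). Of 13 mitochondrially encoded genes mt-Nd3 alone was lower, at −1.01, with a median of −0.46 at percentile 1.10. It was at −0.79 under plain CPM and the stricter cell filter, −0.99 without WT replicate 2 and −0.91 without double knockout replicate 2. Haemoglobin genes had a median of −2.68 at percentile 0. The only measured fibrosis gene, Pdgfb, was higher at 1.24 (0.61 without the clusters led by Havcr1 or Spp1, 0.68 over all cells, 0.85 under a pseudocount of 5), and the only measured female-biased gene was Cyp4a14. The X inactivation list had no measured member.

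**Figure D2:**
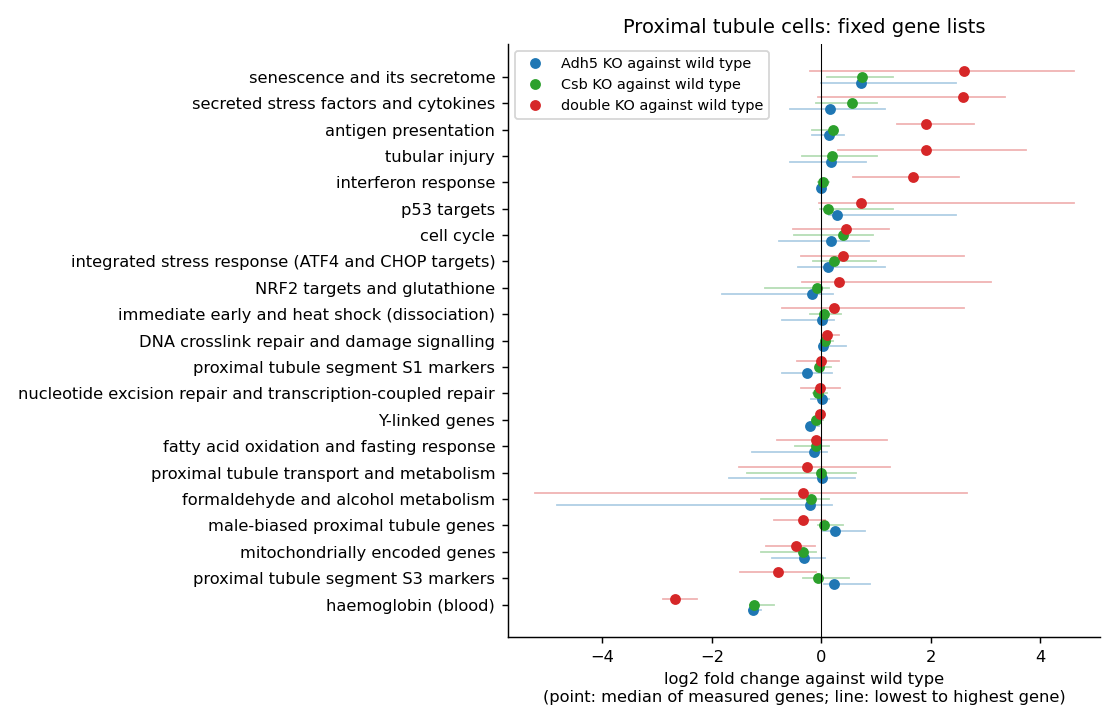
Median log2 fold change of each gene list in proximal tubule cells against WT, with a point per knockout. The members measured differ between the points, with 6, 6 and 15 tubular injury genes in the Adh5, Csb and double knockout, because some pass the minimum of expression only in the double knockout. The antigen presentation list stands at 0.13 in the Adh5 knockout, 0.22 in the Csb knockout and 1.91 in the double knockout.

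Against the Adh5 knockout, the double knockout was read for what Csb loss may add when Adh5 is missing. With 1 pool per genotype, other differences between the pools enter as well. Havcr1 was 208-fold higher (113 to 434) and Lcn2 113-fold. C3, the central complement component, rose 16.5-fold from 2.17 to 35.9 CPM, Ccl2 78.1-fold, Cbr3 34.0-fold, Cyp4a14 24.4-fold, Cyp27b1 14.01-fold and Spp1 10.1-fold. Fgg, a fibrinogen chain, was 7.81-fold higher, the ubiquitin-like Ubd 12.1-fold and Aldh1a1 7.88-fold. Cdkn1a was 4.53-fold higher (4.36 to 4.70) and Gdf15 2.43-fold. Hpd fell 21.2-fold, Mep1b, a brush border protease, 4.78-fold, Slc22a7, an organic anion transporter, 4.69-fold and Cyp2d9 4.57-fold. Azgp1, Cyp7b1, Inmt, Bdh1, Irx3, Dnase1, Lpl and Akr1c14 had log2 fold changes from −1.97 to −1.72, and Adh5 did not differ by the rule (−0.41). In all, 120 of 6964 measured genes were higher and 69 lower. Clusters 3, 6 and 12, led by genes such as Cyp2d9, Hpd and Mep1b, held 13.1%, 9.97% and 4.78% of Adh5 knockout and 2.13%, 1.59% and 0.953% of double knockout proximal tubule cells, so the decreases mix cell make-up with expression.

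Of 15 tubular injury genes, some measured only through their rise, 11 were higher, with a median of 2.27, and all 7 antigen presentation genes were higher, with a median of 1.94. Of 18 p53 targets 5 were higher, with a median of 0.43. Of 7 male-biased genes 2 were lower, with a median of −0.70 at percentile 0, and of 6 S3 markers 3 were lower, with a median of −0.96 at percentile 0. Without the clusters led by Havcr1 or Spp1, Gdf15 (0.94) and Ccl2 (0.97) were not called, and Havcr1 (1.94), Lcn2 (2.40), C3 (2.37), Spp1 (1.84), Fgg (1.39) and Ubd (1.44) were smaller. Lcn2 was 2.83 without double knockout replicate 2 and 4.22 over all cells, and Cyp7b1 −2.53 without double knockout replicate 1. Over all cells C3 (2.84), Ccl2 (4.16), Cbr3 (2.52), Spp1 (2.73) and Ubd (1.90) also moved more than 1.5-fold.

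Against the Csb knockout, the double knockout was read for what loss of the remaining Adh5 may add when Csb is missing, again with 1 pool per genotype. Havcr1 was 48.7-fold higher (Csb knockout libraries at 0.271 and 0.557 CPM), Lcn2 55.5-fold, Cdkn1a 10.5-fold and Gdf15 2.73-fold. Ccl2 and Cxcl1 were 22.1-fold and 15.3-fold higher, C3 10.6-fold, Cfi 8.75-fold, and the fibrinogen genes Fgb and Fgg 10.7-fold and 7.996-fold. Cbr3 rose 14.4-fold, Aldh1a1 8.19-fold and Spp1 7.25-fold. Adh5 fell 19.4-fold, Hpd 13.8-fold, Ndrg2 4.10-fold, Ctxn3 3.99-fold, Dnase1 3.91-fold, Slc22a7 3.59-fold and Klk1, encoding tissue kallikrein, 3.36-fold. In all, 105 of 6943 measured genes were higher and 38 lower. Of 27 transport and metabolism genes 1 was lower, Miox, with a median of −0.39 at percentile 0, and all 7 antigen presentation genes were higher, with a median of 2.07.

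Ccl2 (0.95) and Miox (−0.97) were not called without the clusters led by Havcr1 or Spp1, and Havcr1 (1.82), Lcn2 (2.27), C3 (2.02), Fgg (1.43), Fgb (1.39), Spp1 (1.38), Cxcl1 (1.74) and Cfi (1.76) were smaller there. Miox (−0.95) was not called under plain CPM or CPM without mitochondrial genes, nor Ndrg2 (−0.95) over all cells, where C3 (2.47), Cbr3 (2.32) and Klk1 (−1.11) were smaller, and Lcn2 was 2.70 without double knockout replicate 2.

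The double knockout was also set against the nearest of all other pools, which leaves changes found in no single knockout at that level. Of 7064 measured genes, 88 were higher than in each other pool and 33 lower. The largest log2 differences to the nearest pool were those of Havcr1 (3.73), Lcn2 (3.33), Cbr3 (2.93), Ccl2 (2.77), Spp1 (2.76), C3 (2.75), Aldh1a1 (2.65), Tmsb10 (2.58), Cfi (2.54) and Cd74 (2.51). Cdkn1a (2.14) and Gdf15 (1.26) were higher as well. Hpd (−3.13), Dnase1 (−1.78), Ndrg2 (−1.58), Cyp2d9 (−1.53), Inmt (−1.45), Car3 (−1.38) and Irx3 (−1.33) were lower, as were Hbb-bs, Hba-a1 and Hba-a2. Over all cells, Hbb-bs (−0.18), Hba-a1 (−0.25) and Hba-a2 (−0.23) did not meet the rule against the Adh5 knockout.

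The log2 excess over the sum of both single effects was above 0 in 87 of the 88 higher genes and at least 1 in 75, with a median of 1.77. It was 4.46 for Havcr1, 3.87 for C3, 3.84 for Ccl2 and 2.32 for Cd74. It was 0.84 for Cdkn1a, 0.26 for Gdf15 and −0.06 for Phlda3. Among the 33 lower genes, 18 had an excess of −1 or less, with a median of −1.15, and Hpd had −3.38. The excess has no test, genes were chosen on the same values, and the Csb knockout term also holds the lower Adh5 level of that pool.

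The share of proximal tubule cells with a Cdkn1a UMI, after thinning to 1000 UMIs, was 0.349% in WT, 2.17% in the Adh5 knockout, 0.952% in the Csb knockout and 10.2% in the double knockout. In lymphocytes the shares were 0%, 1.31%, 0.379% and 3.51%, which need not be background, since lymphocytes may express Cdkn1a themselves. Gdf15 was seen in 1.34%, 3.397%, 2.60% and 6.34% of proximal tubule cells, and in 0.430%, 1.14%, 0.474% and 1.46% of lymphocytes. Havcr1 was seen in 1.29% of double knockout cells (lymphocytes 0.146%) and in at most 0.0547% in the other pools. Unthinned, the double knockout shares were 24.0% for Cdkn1a, 21.2% for Gdf15 and 3.63% for Havcr1. The Lcn2 and Krt20 shares in the double knockout (0.971% and 0.127%) lay within counting error of those in its lymphocytes (0.805% and 0.146%), so background cannot be excluded for them. Ddit3 and Mdm2 were seen in 2.39% and 3.55% of double knockout cells, against 0.934% and 2.42% in WT. Lymphocytes give no background level for these 2 genes, since 2.73% of WT lymphocytes held each. Median depth in WT, Adh5, Csb and double knockout was 4254, 4475, 4570 and 3469 UMIs in proximal tubule cells and 3687, 3154, 3043 and 3704.5 in lymphocytes. Of the Adh5 knockout cells 73 were too shallow to thin.

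Immune cells took a larger share of the double knockout than of WT. Macrophages and monocytes made up 7.10% of its cells against 3.42%, T cells 1.94% against 1.10%, dendritic cells 0.809% against 0.255% and neutrophils 0.3999% against 0.127%. B cells made up 0.975% in WT, 2.12% in the Adh5 knockout, 2.45% in the Csb knockout and 2.25% in the double knockout. Urothelial cells were 4.70-fold more frequent in the double knockout and 2.08-fold in the Adh5 knockout. NK cells were 1.53-fold more frequent in the double knockout, but 1.22-fold under the stricter cell filter and 1.18-fold at resolution 0.5. Endothelial cells were 2.00-fold less frequent in the double knockout. Erythroid cells were 3.87-fold less frequent in the Adh5 knockout, 1.84-fold in the Csb knockout and 5.20-fold in the double knockout. In the Adh5 knockout libraries they made up 0.295% (5 cells) and 0.605%. Neutrophils were 1.90-fold less frequent in the Csb knockout, and in the Adh5 knockout intercalated and thick ascending limb cells were 1.68-fold and 1.76-fold less frequent.

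Proximal tubule cells made up 73.8%, 77.7%, 75.2% and 69.9% of the cells in WT, Adh5, Csb and double knockout, and unnamed clusters 2.91%, 3.20%, 2.58% and 3.89%. The liberase digest, the cell filters and the small Adh5 knockout library can set these shares. So can a trait of the WT pool where all 3 knockouts differ from it alike, as for B cells and erythroid cells. Without clusters that also held tubular RNA, the B cell share was 1.32-fold of WT in the Adh5 knockout and 1.38-fold in the Csb knockout, below the 1.5-fold threshold, and 1.80-fold in the double knockout. Endothelium was then at 0.933% in the double knockout against 3.18% in WT. All 205 neutrophils lay in 1 such cluster, so no neutrophil share remains without it. The B cell share was 1.44-fold and 1.41-fold in the Adh5 knockout at resolutions 0.5 and 2. In the Adh5 knockout libraries B cells made up 1.30% and 2.21%, and intercalated cells 1.89% in library 1.

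**Figure D3:**
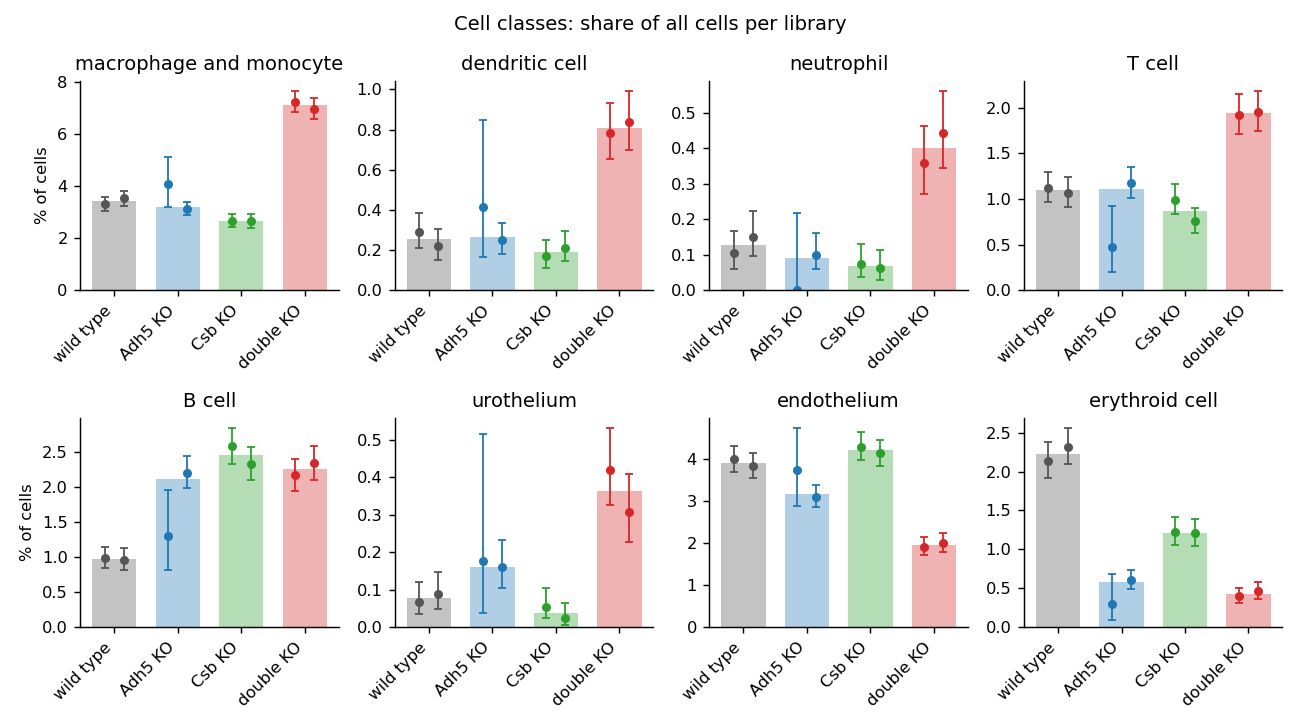
Share of cells in percent for 8 classes and each genotype, with a bar per pool and a point per library. Macrophages and monocytes make up 7.10% of double knockout cells against 3.42% in WT, and erythroid cells 0.428% against 2.23%.

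Outside the proximal tubule, Cdkn1a rose in the double knockout against WT in 8 of 10 classes. In endothelium it rose from 44.8 to 470.1 CPM (10.5-fold), in fibroblasts, pericytes and mesangium from 6.76 to 196 CPM (29.0-fold), in macrophages 7.26-fold, in intercalated cells 9.02-fold and in the thick ascending limb 5.46-fold. With 3 WT UMIs the B cell ratio was 24.7 (8.29 to 121). Endothelium, macrophages (256 CPM) and fibroblasts stood above the 142 CPM of double knockout proximal tubule cells. Free RNA at the mean level of those tubule cells alone could not give this. Macrophage cluster 13 (2155 cells), fibroblast clusters 23 and 27 (1209 and 850) and endothelial clusters 28 and 43 (766 and 225) also held tubular RNA. Droplets mixed with tubule cells higher in Cdkn1a were therefore not excluded. The other 5 classes stood below 142 CPM, at 27.6 CPM in T cells to 106 CPM in intercalated cells, and background was not excluded there. Lcn2 was far more abundant in distal segments than in the proximal tubule, rising from 7.11 to 402 CPM in the thick ascending limb, from 19.1 to 2149.7 CPM in the thin limb and from 2.03 to 40.3 CPM in the distal convoluted and connecting tubule. Gdf15 rose in 6 classes, from 3.46-fold in macrophages to 7.17-fold in the distal convoluted and connecting tubule, but stood in all 6 below its level in proximal tubule cells, so background was not excluded. Mdm2 did not meet the rule in any class where it was measured.

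Macrophages of the double knockout gained the chemokine Ccl7, from 1.97 to 211 CPM, and Mucl1 and Arg1, an arginase of activated macrophages, which had no UMI in WT and were at least 150-fold and 65.9-fold higher. In endothelium Gbp2b was 68.8-fold, the immediate early gene Fos 17.3-fold and Ltc4s, which makes leukotriene C4, 13.2-fold higher. B cells gained Ighg1, an immunoglobulin heavy chain, by at least 790-fold. T cells gained the granzyme gene Gzmc, with a ratio of 164 over 1 WT UMI (29.3 to 6507). In the thick ascending limb the immediate early gene Egr1 was 31.8-fold higher. Adh5, Car3 and haemoglobin genes led the decreases in most classes. The numbers of genes higher and lower were 432 and 794 of 8136 in macrophages, 676 and 381 of 7427 in fibroblasts, 216 and 454 of 7141 in T cells, 129 and 170 of 8882 in endothelium and 112 and 156 of 7536 in the thick ascending limb. Fibroblast and thin limb clusters differed in make-up between the pools, so their values mix composition with expression. Fibroblast clusters 23 and 27, thin limb cluster 35 and macrophage cluster 13 also held tubular RNA, which enters the folds and counts of these classes.

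In the single knockouts, Gbp2b in endothelium was 47.5-fold higher in the Adh5 knockout and 60.5-fold in the Csb knockout, with 4 WT UMIs. Cyp26b1, which breaks down retinoic acid, was 7.02-fold and 8.55-fold higher in the same cells. The cause of these rises was not tested. In Csb knockout macrophages Cd209g and Lyve1, genes of resident macrophages, rose 33.5-fold and 22.5-fold. In Csb knockout B cells Igkv12-44 was at least 112-fold higher. Genes higher and lower were 33 and 64 in macrophages of the Adh5 knockout and 109 and 42 in those of the Csb knockout, and in B cells 76 and 34, and 107 and 21.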

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

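The minimum of 50 cells over the pools compared, below which a share was left out here, was chosen only after NK and urothelial cells had been seen to qualify without it, and the other tests were not. A difference between groups was looked for in Csb knockout against WT and in double knockout against Adh5 knockout. The first also holds a lower Adh5 level, 46.1% of WT in the Csb knockout pool, so it is not an effect of Csb loss alone. A gene that met the rule of size upward in 1 of these and downward in the other was singled out, as was a share that moved at least 1.5-fold in opposite ways with the libraries of each pair apart. In each case the difference itself was not tested, because each genotype is 1 pool.

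Ctxn3, a small membrane protein, was higher in the Csb knockout than in WT (4.25 to 19.6 CPM, log2 1.97) and lower in the double knockout than in the Adh5 knockout (11.6 to 4.90 CPM, log2 −1.10), a difference of −3.07. Igha, the immunoglobulin A heavy chain, moved from 1.80 to 13.96 CPM and from 11.2 to 4.496 CPM, a difference of −3.57. Gsta2, a glutathione transferase, moved the other way, from 861 down to 419 CPM in the first comparison and from 245 up to 798 CPM in the second, a difference of 2.74. Neutrophils made up 0.127% of WT cells and 0.0671% of Csb knockout cells, 0.527 of the WT share, but rose from 0.0916% in the Adh5 knockout to 0.3999% in the double knockout, 4.37-fold. The ratio of these folds was 8.28. All 205 neutrophils lay in 1 cluster that also held tubular RNA, so this value ends where such clusters are left out. No explanation of these 4 differences was tested.

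A signal in data outside the comparisons was found in cells of unnamed clusters, which none of the class comparisons uses. In the double knockout Cdkn1a stood at 210.4 CPM there against 36.8 CPM in WT, a 5.72-fold difference. Gdf15 stood at 129 against 39.99 CPM (3.23-fold), and Lcn2 at 136 against 6.28 CPM (21.6-fold). Mdm2 was at 34.5 and 33.9 CPM, a 1.02-fold difference. Unnamed clusters mix cell types whose proportions were not compared, and no biological explanation was tested.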

How the results depend on the processing

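Alternatives chosen only after the result was seen were the floor of 2000 UMIs per cell, shares without clusters holding tubular RNA, proximal tubule cells without the clusters led by Havcr1 or Spp1, and lists limited to members at 10 CPM or more in WT. No named gene that met the rule of size reversed its direction under any alternative run. Among single values, 3761 of named genes, 1162 of list medians, 332 of cell shares, 97 of shares of cells with a UMI and 12 of targeted genes stayed within the counting error or spread set for them, and 1964, 546, 196, 71 and 2 moved outside it. Another 9 list medians were counted as reversed in sign. That count does not hold every change of sign. It leaves out secreted stress factors in Adh5 knockout against WT, limited to members at 10 CPM or more in WT. It also leaves out immediate early and heat shock genes there, which moved from 0.0146 to −0.00295 under the same limit. Adh5 in the Adh5 knockout was at 3.47% of WT under plain CPM, Adh5 in the double knockout at 2.77% under plain CPM and 2.19% under the stricter cell filter, and Ercc6 in the double knockout at 69.8% under plain CPM.

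Where each library counted as a sample, tests across 15011 genes called more genes at an adjusted p under 0.05 and a 2-fold change. They require no minimum of 10 CPM and rest on the variation between libraries (coefficient 5.06%), and the cause of the larger counts was not tested. These calls compare libraries, not genotypes. The edgeR quasi-likelihood test called 156 genes higher and 156 lower in Adh5 knockout against WT, 186 and 63 in Csb knockout against WT, 1106 and 387 in double knockout against WT, 1055 and 303 against the Adh5 knockout, 910 and 264 against the Csb knockout, and 570 and 137 against all others. With the library number as a replicate block, which pairs libraries that share only a number, the counts were 154 and 146, 175 and 58, 1092 and 379, 1000 and 299, 895 and 257, and 548 and 131. DESeq2 called 129 and 108, 129 and 45, 841 and 306, 731 and 265, 627 and 182, and 393 and 113.

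The minimum of expression changes how many genes enter. At 30 CPM, 13 genes were higher and 20 lower in the Adh5 knockout, 5 higher in the Csb knockout, 49 higher and 48 lower in the double knockout against WT, 48 higher against the Adh5 knockout, 41 higher and 21 lower against the Csb knockout and 31 higher against all others. All 49 and 48 were among the calls at 10 CPM. At 1 CPM and with no minimum of UMIs, the counts were 37 and 49, 42 higher, 294 and 117, 281 and 107, 219 and 64, and 174 higher. A pseudocount of 5 left 8 genes higher in the Csb knockout, 44 lower in the double knockout against the Adh5 knockout and 17 lower against all others.

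Summing all cells in place of proximal tubule cells gave 368 higher genes in the double knockout against WT, 357 against the Adh5 knockout, 338 higher and 71 lower against the Csb knockout and 298 higher against all others, since other classes and their shares then enter. Without the clusters led by Havcr1 or Spp1 the numbers of higher genes were 69, 64, 53 and 38. CPM without mitochondrially encoded genes gave 190 higher genes in the double knockout against WT, including all 124 of the main calls.

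Plain CPM raised the median of all measured genes by 0.21 in double knockout against WT and by 0.12 against either single knockout, and CPM without mitochondrial genes by 0.16 and 0.12. In double knockout against WT the higher share of calls was then 77.3% and 76.3%, beside 124 higher and 75 lower, and 53 and 57 of the 75 lower genes were shared. Against the Adh5 knockout it was 76.0% and 77.4%, beside 120 and 69. In Csb knockout against WT it was 62.1% under plain CPM and 37.0% with DESeq2 factors, beside 13 and 14.

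Limited to members at 10 CPM or more in WT, tubular injury genes were at −0.0235 in Adh5 knockout and −0.00790 in Csb knockout against WT. These medians cover 5 genes in place of 6, because Il34 is left out. Under the same limit, secreted stress factors in Adh5 knockout against WT moved from 0.159 (percentile 95.6, 4 genes) to −0.505 (percentile 0.04, 3 genes). The cause of the other changes of sign of list medians was not tested. Transport and metabolism genes in Csb knockout against WT were at 0.0873 under plain CPM, 0.0375 without mitochondrial genes and 0.0429 under the stricter filter, and fatty acid oxidation genes at 0.00108 under plain CPM. Fatty acid oxidation genes in double knockout against Adh5 knockout were at −0.0788 over all cells. Immediate early genes were at −0.00913 in double knockout against Adh5 knockout and −0.0131 against Csb knockout (0.34 and 0.24 with all clusters), without the clusters led by Havcr1 or Spp1.

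Leaving out 1 library at a time gave 22 to 52 higher and 30 to 55 lower genes in Adh5 knockout against WT, with the upper ends when only its small library was left. It gave 3 to 6 lists below percentile 2.5 there, and Adh5 at 2.97% to 3.30% of WT. Lone libraries were read by the rule of size with no test. Higher and lower genes ranged from 11 to 13 and 14 to 17 in Csb knockout against WT, 121 to 125 and 73 to 80 in double knockout against WT, 118 to 158 and 66 to 85 against the Adh5 knockout, 104 to 105 and 37 to 39 against the Csb knockout, and 86 to 91 and 31 to 33 against all others. Summed over the other classes, higher genes ranged from 371 to 1371 and lower genes from 428 to 6700 in the Adh5 knockout (307 and 722 with all libraries), and from 440 to 802 and 277 to 599 in the Csb knockout (492 and 290). In the double knockout they ranged from 1754 to 2400 and from 2477 to 3385 (2048 and 2969). Plain CPM gave 433 lower genes in the Adh5 knockout.

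The number of classes with a larger share in the Adh5 knockout was 2, and 1 at resolutions 0.5 and 2 and without clusters holding tubular RNA, with 1 to 3 over single libraries left out. In the Csb knockout 1 class had a larger share, against 2 under the stricter filter and at resolution 2, and 0 without clusters holding tubular RNA. The classes with a smaller share numbered 2, against 1 without those clusters and 1 to 2 over single libraries left out. In the double knockout 6 to 8 classes had a larger share over single libraries left out. The cause was not tested. The small Adh5 knockout library, with 1694 cells, limits all values of rare classes in that genotype, and Havcr1, Lcn2 and Ccl2, at under 1 CPM in the 3 other pools, rest on few UMIs outside the double knockout.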

Other observations

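The tests of a change of scale between the pools, of immune RNA read gene by gene and of genes of 200 to 500 kb were chosen only after the result was seen, as were the floor of 2000 UMIs, the clusters left out and the clock genes. The clock output gene Dbp stood at 98.8, 69.6, 72.7 and 50.9 CPM in WT, Adh5, Csb and double knockout proximal tubule cells (log2 −0.94 in double knockout against WT), and Nr1d1 at 23.6, 22.9, 14.6 and 12.2 CPM (−0.89). The other 8 of 10 clock genes read ran from −0.85 (Ciart) to 0.66 (Arntl), with Clock at 0.32 and Nr1d2 at −0.15. Ciart, Arntl, Per1 and Per2 lay below the minimum of expression, so the rule of size was not applied to them. None of the measured clock genes met it.

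Adh5, not listed as targeted in the Csb knockout, stood there at 46.1% of the WT level in proximal tubule cells. A change of scale between the pools is argued against by unscaled UMIs per cell, whose median log2 ratio to WT over 6791 measured genes was 0.11 (quartiles 0.03 and 0.19) where that of Adh5 was −1.01. In 10 of 10 other classes the ratio to WT was 0.410 to 0.525, near the level that 1 working copy of Adh5 would give. A mixture of mice with both copies and with none would also lower all classes alike, and free tubular RNA enters each class. These ratios therefore do not single out 1 copy. After the Adh5 UMIs of WT cells were thinned to the observed ratio of 0.514, 24.5% of cells held one at 2000 UMIs per cell. In the Csb knockout 24.6% did (24.0% to 25.2%). Because the observed ratio was used, any even lowering across cells gives this share, so it does not single out 1 copy. A mixture of mice with both copies and with none would give 21.4%, which is 3.26 percentage points below the observed share (2.66 to 3.87). This range spans the bound of 3 points set beforehand, so that test gave no verdict. The observed share exceeds that of the mixture by more than counting error. The mixture was computed from separate pools, however, without the free Adh5 RNA that cells of 1 mixed pool would share. The difference therefore does not decide against such a mixture. Variation between pools is not covered by this range. A stretch of chromosome that came with the targeted allele may add to the lower Adh5 level. Lamtor3, the only gene lower in the Adh5 knockout among 21 measured within 5 Mb, stood at 64.7% of WT in the Csb knockout. The call of Lamtor3 ended without Adh5 knockout replicate 2 (log2 −0.87). Slc39a8, within the same 5 Mb, was called higher in the Adh5 knockout, at 224.5% of WT, and stood at 135.7% in the Csb knockout.

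Antigen presentation genes were higher in proximal tubule cells of the double knockout, with a median log2 fold change of 1.91 against WT. A lower UMI limit for calling cells is argued against by a median of 1.90 at a floor of 2000 UMIs. Clusters led by Havcr1 or Spp1 as the whole source are argued against by a median of 1.15 without them (1.04 to 1.26 over library pairs), though the rise was then smaller. These are clusters 8 and 33, and cluster 8 has Iigp1, Fgg, Ifit3 and Cxcl10 ahead of Spp1. The smaller rise is therefore not that of injured cells alone. Immune cell RNA in tubule droplets, read from the median marker of macrophages, dendritic, B and T cells, accounted for 9.78% of the rise of Cd74 and 8.32% of that of H2-Ab1 (14.5% and 12.5% from the upper quartile of markers), which argues against it as the main source. For H2-Aa (19.1%) and H2-Eb1 (21.1%) it cannot be told apart from a rise within tubule cells, since the upper quartile gave 28.5% and 31.4%, above the bound of 25%. The highest marker, Plac8, would give 180.5% for Cd74, but it was already at 30.2 CPM in WT tubule cells and its source was not tested, nor was a response of the tubule cells themselves.

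Of 39 measured genes of at least 500 kb in double knockout against WT, 6 were lower (Fhit, Lrmda, Immp2l, Dpyd, Sugct and Cpq), 1 was higher (Nrg1, from 5.69 to 21.9 CPM) and the others were neither, with a median of −0.27. Less nuclear RNA in the double knockout droplets would lower both nuclear RNAs read. Malat1 was slightly lower (log2 −0.18) and Neat1 was higher (0.46), so the prediction that both fall was not met. Levels of 2 RNAs can change for other reasons, so a small loss of nuclear RNA is not excluded. Fewer transcripts of longer genes may account for the lower levels of very long genes, but the values leave this open. The 235 genes of 200 to 500 kb had a median of −0.09 at percentile 0 of matched random lists, while genes under 10 kb had a median of −0.11. In the Adh5 and Csb knockouts, genes of 200 to 500 kb were at percentile 4.78 and 10.6, and all genes of at least 200 kb, which include those the pattern was seen in, at 0.02 and 2.36. Lrmda (−2.55), Fhit (−1.70) and Immp2l (−1.32) were already lower in the Adh5 knockout alone and at −0.99, −0.85 and −0.76 in the Csb knockout, short of the rule, and no biological explanation was tested.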
